A study of Danio rerio with 22 samples.

How the data were processed

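The 22 arrays were 1-colour 44k zebrafish oligonucleotide arrays hybridised with Cy3-labelled RNA from liver pools. Per the labels, each pool held 4 livers of adult males, RNA was extracted with TRIzol and purified on columns, its integrity number was above 8.1, and 100 ng were labelled by oligo-dT priming. The design text gives 5 replicates for each of 3 groups at 2 times, and 22 arrays were analysed here. The series title names cadmium compounds while the design text, the protocol and every sample label name silver. The p-values measure the spread between pools.

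Each array file held spot intensity, background and flags in the units of the scanner software. The values used are background-corrected signal intensity and mean and background intensity per the file headers, and the deposited flags are other values of 0 or 1. Per the deposited processing text, the authors took the intensity with a floor of 1, averaged replicate spots by geometric mean, took log2, applied quantile normalization, centred each gene and kept probes present or marginal in 80% of the samples of 1 of the 6 conditions. That text names no test and says that copper and silver samples were handled as separate projects.

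Here the background-corrected intensity was floored at 1, spots flagged as outliers were set missing, replicate spots were averaged on the log2 scale and arrays were quantile normalized with limma. Signal over background set the depth. Of 43603 probes (43803 spots without controls), 33792 were well above background on at least 3 of the 22 arrays and were tested. Probe names were matched to current gene names by accession (27850 probes), symbol (3793) or synonym (1079), and 10881 had no match. Each gene was represented by its tested probe with the highest mean, which gave 19933 genes (14289 with a symbol), 19860 of them with a value on every array. No genome of the build that the probes refer to was at hand, so coordinates are those of the array annotation (Zv9). Where a group was not well above background for a gene, its fold change is given as a bound against that limit.

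One linear model of the 6 groups was fitted to all arrays with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 for correlated blocks, and tested with the moderated statistic, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The comparisons were nanoparticle and ionic silver against control at each time, nanoparticle against ionic silver at each time, the difference of each exposure effect between times, and control at 21 d against control at 3 d. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

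The 32 gene lists were fixed before the data were examined, as were the groups, the comparisons, most alternative settings and the rule for naming genes. They hold 22 pathways and 10 cell types, each with at least 5 measured genes. The pathway lists were metal handling, antioxidant and glutathione, heat shock, unfolded protein response, DNA damage, cell cycle, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, xenobiotic metabolism, estrogen responsive, bile acid and sterol transport, glucose metabolism, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, proteasome, complement and coagulation, acute phase and inflammation, interferon response, circadian clock and extracellular matrix. The cell type lists were markers of hepatocytes, exocrine pancreas, endocrine pancreas, intestine, erythrocytes, leukocytes, endothelial and stellate cells, bile ducts, gonad and germ cells, and muscle. The estrogen responsive and gonad lists share 6 genes, the proteasome and interferon lists 4, and complement shares 4 with hepatocyte and 4 with leukocyte markers. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 32 lists. Genes were also adjusted over each list alone.

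Genes to name were drawn by rule: the 8 largest rises and the 8 largest falls among called genes whose group ranges did not overlap, up to 4 called genes of each list, 2 genes of a called list without called members, the 5 genes with the lowest p where under 8 passed, and 10 genes named in advance (among them mt2, hsp70l, hmox1a, gstp1, cat, sod1, cyp1a, vtg1 and hamp). The text prints some of the genes that the rule returned, picked after values were seen. No probe carried the symbol gstp1.

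Vitellogenin means over 7 genes were compared by exact permutation tests of the arrays, two-sided. Sharing of genes between exposures was set against independent draws and against 100 simulations that keep the shared controls and have no exposure effect. Other splits of the arrays of each comparison, up to 100, were refitted in the same way.

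Slide and scan day were read from the file headers. The 6 slides each held 1 to 3 arrays of a group, slides 1 to 3 were scanned on one day and slides 4 to 6 on another. Slide 1 held 3 controls and 1 ionic array of 3 d, slide 2 held 2 ionic and 2 nanoparticle arrays of 3 d, slide 3 held 2 nanoparticle arrays of 3 d and 2 controls of 21 d, slide 4 held 1 control and 3 ionic arrays of 21 d, slide 5 held 1 ionic and 2 nanoparticle arrays of 21 d, and slide 6 held 3 nanoparticle arrays of 21 d. The estimated correlation within slides was 0.119. Replicate numbers were tested for pairing: at 3 d 0 of 7 pairs with the same number, and at 21 d 5 of 9, had correlated deviations above 0.1. Pairing was not seen at 3 d and stays open at 21 d, and arrays were not treated as pairs. No pair of arrays was a duplicate, the lowest SD of a difference being 0.816.

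Alternatives changed one choice at a time over 45 settings, of which 22 leave out 1 array and 6 were added after the data were seen. They covered scaling by the 75th percentile, normexp background correction with an offset of 50, the filter on dim probes (none, or at least 11 arrays), every probe tested alone, the arrays in the fit, replicate and slide terms, scan day, array weights, a threshold of 0.01, a fold of at least 2 and marker means as covariates. A count was taken as moved beyond 1.5 times, and a gene that passed under neither setting was taken as alike whatever its sign. On simulated data with added changes of 4-fold in 50 genes, the fits recovered 52% to 70% of them at the arrays' own spread, and a shifted list was found in all 6 comparisons. The simulated genes varied independently of each other, so this does not test the list calls for lists of correlated genes.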

Results

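The 22 arrays measured liver RNA of adult zebrafish, male per the labels, kept in clean water, in water with 20 nm maltose-coated silver nanoparticles or in water with ionic silver, both at 0.01 mg/L. Each replicate was a pool of 4 livers. The groups analysed here held 3 control, 4 nanoparticle and 3 ionic arrays at 3 d, and 3 control, 5 nanoparticle and 4 ionic arrays at 21 d. The series title names cadmium compounds, whereas the design text, the protocol and the sample labels name silver, and the groups follow the labels. Between 54.1% and 69.6% of the probes on an array were well above background. The 75th percentile of intensity averaged 174, 269 and 219 in the 3 d controls, ionic and nanoparticle arrays, and 196, 639 and 301 in those of 21 d. Array intensities correlated within a group at 0.843 to 0.97 across genes, which are not independent replicates. The number of arrays limits the precision of every value.

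Metallothioneins bind metal ions through clustered cysteines and are made in response to zinc, cadmium, copper and silver. The mt2 transcript (probe on Zv9 chromosome 18: 17195003–17195060) stood at a log2 intensity of 11.27 ± 0.33 in the 21 d controls, 14.13 ± 0.21 with nanoparticles and 15.86 ± 0.48 with ionic silver. It rose 7.26-fold with nanoparticles (log2 fold change 2.86, SE 0.291, limma adjusted p = 0.000206) and 24.0-fold with ionic silver (4.59, SE 0.304, adjusted p = 1.79e-07). The nanoparticle arrays lay below the ionic arrays by a log2 fold change of −1.73 (SE 0.267, adjusted p = 5.33e-05). At 3 d mt2 averaged 11.79 ± 0.27 in controls, 13.23 ± 0.41 with nanoparticles and 13.11 ± 0.60 with ionic silver. The 3 d differences of 1.44 and 1.32 did not pass (adjusted p = 0.127 and 0.109), although every exposed array lay above every control array at both times. The ionic effect on mt2 was larger at 21 d than at 3 d by 3.26 (adjusted p = 0.000165), and the same test for nanoparticles gave 1.42 (adjusted p = 0.189). In both exposures 4 of the 5 mt2 probes moved the same way. No slide held nanoparticle arrays beside controls of the same time. With slide as a fixed term the 21 d mt2 rise was 4.06 for ionic silver (adjusted p = 0.000272), and for nanoparticles it was 2.03 (SE 0.591) and no longer passed (adjusted p = 0.972). A fit within slide gives the same ionic estimate, since both rest on slide 4, with 1 control and 3 ionic arrays. The nanoparticle minus ionic value was −2.03, from slide 5 with 1 ionic and 2 nanoparticle arrays. At 3 d the nanoparticle and ionic differences were 2.52 and 1.99 with slide as a fixed term. Both rest on 1 ionic array, that of replicate 1, the only exposed array on the slide of the 3 d controls. The nanoparticle value reaches the controls through it, by way of another slide. The larger ionic effect at 21 d than at 3 d no longer passed with slide as a fixed term (2.07, adjusted p = 0.103), which gives the same estimate as within slide. The nanoparticle value of that test was −0.49 with the slide term (adjusted p = 0.848).

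**Figure D1:**
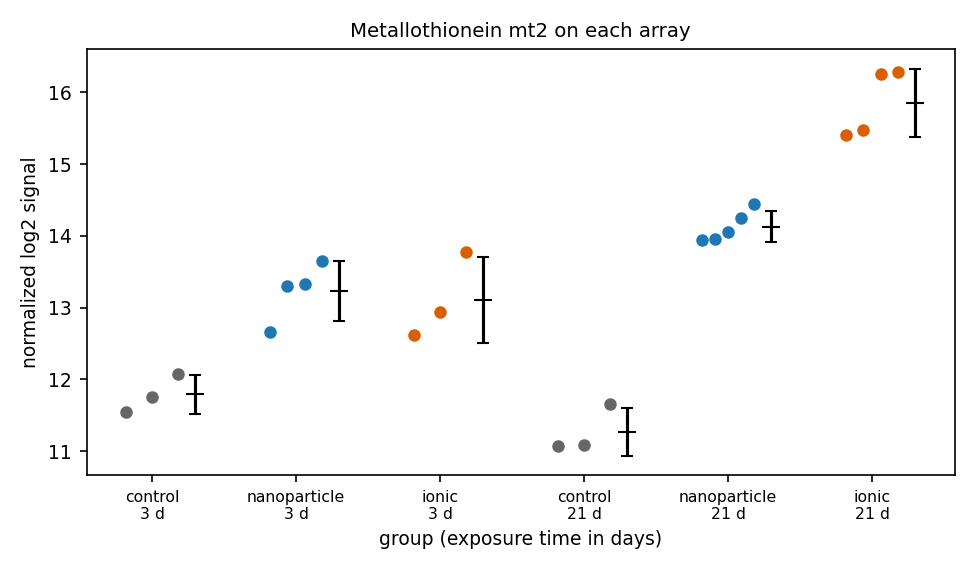
Log2 intensity of mt2 on each array (points) in the 6 groups, with the group mean and SD (bars). At 21 d the means were 11.27 in controls, 14.13 with nanoparticles and 15.86 with ionic silver.

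Immediate early genes encode transcription factors and phosphatases that switch on within minutes of a stimulus and lead the transcriptional response to growth factors and stress. After 3 d of nanoparticle exposure egr1, dusp2, ier2a and ier2b were lower than in controls. The dual-specificity phosphatase dusp2 (chromosome 8: 42272993–42273052) fell from 12.34 ± 1.02 in controls to 7.96 ± 0.31, a log2 fold change of −4.38 (SE 0.572, adjusted p = 0.00431). The zinc finger factor egr1 (chromosome 14: 22335614–22335673) was at least 12.9-fold lower (adjusted p = 0.0106), since 0 of the 4 nanoparticle arrays were well above background for it. The log2 fold changes of ier2a and ier2b (chromosome 11: 31914066–31914127) were −3.07 and −2.48 (adjusted p = 0.00887 and 0.0106). The insulin receptor substrate irs2a moved the same way and missed the threshold (−1.58, adjusted p = 0.0659). In limma 6 of 19933 genes passed, 1 up (ENSDART00000149112) and 5 down (the fifth was LOC570258), and 2014 had an unadjusted p under 0.05. Of all genes 17.9% had group ranges that did not overlap, against 5.71% by chance. The 21 d controls held these transcripts at a level between those of the 3 d controls and the 3 d exposed arrays, with dusp2 at 9.06 ± 1.06 and egr1 at 4.61 ± 1.49. With limma fitted to the 3 d arrays alone 0 genes passed. Slide as a fixed term called 353 genes, 76.5% of them up against 16.7% as reported, and ier2a (−3.16, SE 0.939, adjusted p = 0.0866) and ier2b (−2.07, SE 0.767, adjusted p = 0.148) no longer passed. In the slide fit dusp2 stood at −5.67 and egr1 at −6.27, where the size for egr1 depends on the floor. That fit reaches the 3 d controls through 1 ionic array. With array weights 718 were called, 51.3% up.

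Cholesterol synthesis runs from acetyl-CoA through the mevalonate pathway under the control of sterol-regulated transcription factors. Of its 27 genes, 12 were up and 2 down in the 3 d nanoparticle arrays when adjusted over the list alone, and 0 passed over all genes. The median log2 fold change of the list was 0.82, with acat2 at 1.78 (adjusted p = 0.131). Camera with a preset correlation gave an adjusted p of 5.96e-08 (adjusted p = 0.328 with an estimated correlation), and fry, which tests whether the genes of a set move on balance one way, gave 0.0321. The proteasome list, which holds the subunits of the protein-degrading complex, had a median of 0.25 (adjusted p = 1.42e-07, or 0.434 with an estimated correlation, and 0.0321 with fry). Its member psmd8 stood at 0.98 (adjusted p = 0.131), and 2 of its 56 genes were up when adjusted over the list alone. Oxidative phosphorylation (median 0.30), ribosome biogenesis (0.23), cell cycle (0.41) and erythrocyte markers (0.31) were also higher, with camera values of 2.14e-10, 2.65e-05, 0.00963 and 0.00981. The circadian clock list was lower (median −0.43, adjusted p = 0.000105, or 0.478 with an estimated correlation). The estrogen responsive list had a median of −0.02 and 9 of its 24 genes down when adjusted over the list alone (camera 0.0296). Markers of other cell types moved at the same time, with medians of 1.23 for exocrine pancreas, 1.12 for endocrine pancreas and 1.31 for gonad (camera 3.49e-05, 0.0341 and 0.00187). Hepatocyte markers had a median of 0.18 (camera 0.0146), which turned to −0.26 with the 75th percentile shift. Where not given, the value with an estimated correlation was 0.928. A fit with slide as a fixed term called 10 lists, 40% of them up against 83.3% of the 12 as reported. In it cholesterol synthesis stood at 0.39 (camera 0.479), oxidative phosphorylation at 0.13 (camera 0.157), exocrine pancreas at −0.65 and endocrine pancreas at −3.23, none of them called, while cell cycle (2.92), ribosome biogenesis (0.86) and the proteasome (0.43) were called as higher. The slide fit reaches the 3 d controls through the ionic array of replicate 1. Its cell cycle mean was 9.65, against 5.2 to 7.85 on the nanoparticle arrays and 5.47 to 6.05 on the controls. The value of 2.92 is therefore not a measure of the nanoparticle arrays alone. Over the 6 comparisons between groups of the same time, 0 lists passed camera with an estimated correlation.

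The same immediate early genes were lower with ionic silver than in controls at 3 d, together with transcripts for the collagen chaperone hsp47, which folds procollagen in the endoplasmic reticulum. The hsp47 genes serpinh1b (chromosome 15: 28732398–28732457) and serpinh1a (chromosome 10: 39887197–39887256) had log2 fold changes of −2.42 (SE 0.318, adjusted p = 0.00552) and −2.15 (adjusted p = 0.0334), and serpinh1a was also lower in the 21 d than in the 3 d controls (−2.12). Log2 fold changes were −6.41 for the zinc finger factor egr2a (adjusted p = 0.00932) and −4.60 for dusp2 (adjusted p = 0.00552). Expression of egr1 was lower too (adjusted p = 0.0141), with 1 of the 3 ionic arrays well above background, so its size depends on the floor (−5.94 to −1.65 over the settings). The values for ier2a and ier2b were −3.26 and −2.3. The homeobox gene pitx1 (chromosome 21: 44148711–44148770) was higher (adjusted p = 0.00816), and only 1 of the 3 control arrays was well above background for it, so the size of the difference depends on the floor (log2 fold changes of 1.94 to 6.28 over the settings). The tight junction gene cldn7a was at least 3.82-fold higher (adjusted p = 0.0334), as the controls were not well above background. Over all genes limma called 15, 2 up and 13 down, and 2623 had an unadjusted p under 0.05. Group ranges did not overlap for 23.0% of genes, against 10% by chance. When the ionic array of replicate 1 was left out, 0 genes passed, and the value for dusp2, ionic vs control, 3 d, was −4.16 (SE 0.662, adjusted p = 0.0506), against −4.60 (SE 0.612) with it. Slide 1 alone held ionic and control arrays of 3 d together, and its ionic array was that of replicate 1. A fit within slide called 1886 genes, 62.1% of them up against 13.3% as reported, with dusp2 at −5.47 (adjusted p = 0.0052). It compares that 1 ionic array with the controls and takes its spread from other groups.

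In the 3 d ionic arrays the unfolded protein response list, which holds the chaperones and sensors of the endoplasmic reticulum, had a median of −0.61 (camera adjusted p = 2.17e-06). Its member chac1 stood at −2.43 (adjusted p = 0.0929). The heat shock list holds mostly cytosolic and mitochondrial chaperones, and also the hsp47 genes. It had 2 of 37 genes down over all genes, which were serpinh1b and serpinh1a. Adjusted over the list alone 5 were down (median −0.23, camera 0.038). The cytosolic chaperone hsp70l, at 1.63, did not pass (adjusted p = 0.524). Cell cycle genes were higher (median 1.58, camera 5.4e-16), with 1 of 71 up when adjusted over the list alone. Fatty acid oxidation (median −0.26) and estrogen responsive genes (−0.45, with 11 of 24 down when adjusted over the list alone) were lower, both with camera values below 0.01. Proteasome (0.23), interferon response (0.32), extracellular matrix (0.34), leukocyte (0.39) and biliary lists (0.37) were higher, with camera values of 0.000439, 0.00678, 0.038, 0.0123 and 0.0203. Exocrine pancreas markers had a median of 2.24, intestine markers 1.51, endocrine pancreas markers 1.35, muscle markers 1.27 and gonad markers 1.69. These 15 calls gave 0.771 with an estimated correlation, except leukocyte markers at 0.814, and fry called 0 lists. Fitted within slide, the cell cycle median was 3.78, that of the unfolded protein response −0.73, that of the gonad list 5.61 and that of exocrine pancreas 1.15 (camera 0.17). The array of replicate 1 had a gonad marker mean of 9.48, against 4.12 and 3.18 in the others, and a cell cycle mean of 9.65, against 6.27 and 6.49. Fitted without the 2 arrays of 3 d with most gonad RNA, of which this was 1, the medians were 0.55 for cell cycle (camera 0.000185) and −0.23 for gonad markers (camera 0.927).

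Comparing the exposures directly at 3 d, serpinh1b was higher with nanoparticles than with ionic silver, at 7.81 ± 0.46 against 4.36 ± 0.37 (log2 fold change 3.45, SE 0.297, adjusted p = 1.52e-05). The inositol-cleaving oxygenase miox (2.70), the chaperone adaptor ttc4 (1.51) and the steroid and fatty acid elongation enzyme hsd17b12b (1.06) were higher too, each with an adjusted p of 0.0085. The phosphorylase kinase subunit phkg2 (1.25) and the RNA polymerase subunit polr3k (1.15) passed at 0.0373, and pitx1 was lower (adjusted p = 0.035). Limma called 11 genes, 9 up and 2 down, with 2873 at an unadjusted p under 0.05. Ranges did not overlap for 14.4% of genes (5.71% by chance). The heat shock list was higher (median 0.21, camera 0.00172, fry 0.0167), with 4 of 37 up when adjusted over the list alone. Its only member called over all genes was serpinh1b. The unfolded protein response (0.41), cholesterol synthesis (0.48), fatty acid oxidation (0.21), oxidative phosphorylation (0.28), ribosome biogenesis (0.34), complement and coagulation (0.30) and erythrocyte lists (0.36) were higher by camera. Cell cycle (−1.07), interferon response (−0.39), exocrine pancreas (−1.05), intestine (−3.35), leukocyte (−0.33) and muscle lists (−1.38) were lower. The cell cycle difference rests largely on ionic replicate 1, with a cell cycle mean of 9.65 against 6.27 and 6.49 in the other ionic arrays and 5.2 to 7.85 in the nanoparticle arrays. Its median was −0.39 (camera 0.00977) without the 2 arrays of 3 d with most gonad RNA. The value with an estimated correlation was 0.715 for these lists and 0.872 for complement and coagulation. Fitted within slide, serpinh1b stood at 3.54 (adjusted p = 0.00292) and 2 genes passed. In that fit miox (2.88, SE 0.537), ttc4 (1.66, SE 0.319), hsd17b12b (1.06, SE 0.214), phkg2 (1.38), polr3k (1.31) and pitx1 did not pass (adjusted p = 0.168 to 0.218).

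Dusp2, egr1, ier2a and ier2b passed in both exposures at 3 d, all 4 of them down. The shared count was 0 without ionic replicate 1, with the 3 d arrays alone, with replicate number as a block and without the 2 arrays of 3 d with most gonad RNA, and 319 with slide as a fixed term, 77.7% of them up. In that slide fit both exposures reach the controls through 1 ionic array, that of replicate 1. Independent draws would share 0.00326 downward genes, and the highest shared count in 100 simulations with no exposure effect and the same controls was 0. The correlation of the exposure effects across genes was 0.561, against a mean of 0.517 in these simulations. The covariance was 0.373, within the simulated range of −0.04 to 0.896, which holds what shared controls alone give.

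Vitellogenins are the egg yolk precursors that estrogen switches on in the liver of female fish. The mean log2 intensity of vtg1 to vtg7 was 16 ± 1.66 in the 3 d controls, 9.75 ± 2.91 with nanoparticles and 8.04 ± 2.81 with ionic silver. At 21 d it was 16.64 ± 0.74, 11.67 ± 2.95 and 11.71 ± 3.34. Exposed minus control differences were −6.25 and −7.96 at 3 d and −4.97 and −4.93 at 21 d, nanoparticle first, and every exposed array lay below every control of its time. Two-sided exact permutation tests gave p = 0.0286, 0.1, 0.0536 and 0.0857, or 0.1 each after adjustment over the 4, and those of 3 d were the smallest that 3 against 4 and 3 against 3 arrays allow. In limma vtg1 (chromosome 22: 25203653–25203712) at 3 d gave −6.89 and −9.21 (adjusted p = 0.358 and 0.169). At 21 d with nanoparticles vtg3 passed at −5.25 (adjusted p = 0.0313), the estrogen receptor esr1 at −1.51 (adjusted p = 0.0211) and the protease gene nots at −5.17 (adjusted p = 0.0102). With slide as a fixed term vtg3 stood at 0.39, while vtg1 at 3 d stood at −14.06 with nanoparticles and −11.37 with ionic silver. Both of these 3 d values rest on the 1 ionic array beside the 3 d controls.

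After 21 d of nanoparticles hmox1b, atp7b, hspe1 and hspd1 were among the genes that rose. The haem oxygenase hmox1b had a log2 fold change of 3.48 (SE 0.727, adjusted p = 0.00864), from 9.03 ± 1.35 to 12.51 ± 1.31. The copper and silver pump atp7b rose by 1.44 (adjusted p = 0.00926), the mitochondrial chaperonins hspe1 and hspd1 by 0.97 and 0.80 (adjusted p = 0.00645 and 0.0234), and the endoplasmic reticulum factor manf by 1.48. The enterohepatic hormone fgf19 rose by 3.61 (adjusted p = 0.00804), while the bile salt pump abcb11a fell (−2.72, adjusted p = 0.0132). The sulphotransferase sult2st3 fell (adjusted p = 0.00517), as did cyp2aa1 (−1.55) and jun (−1.14). Catalase (cat, 0.70), hepcidin (hamp, 3.46) and the iodide carrier slc5a5 rose, with adjusted p of 0.0413, 0.0449 and 0.0114. The gut amino acid carrier slc6a19b (−6.45), pvalb9 (−6.69) and the lectin itln2 fell as well. For sult2st3, slc5a5 and itln2 no size is given, because in 1 of the groups a single array was well above background (itln2 ran from −7.27 to −2.47 over the settings). Limma called 3528 genes, 1514 up and 2014 down, of which 2623 changed at least 2-fold. Ranges did not overlap for 22.4% of genes, against 3.57% by chance. All exposed arrays of 21 d were scanned on one day, and 2 of the 3 controls, replicates 1 and 4, on another. The count was 32 with scan day as a fixed term, 10 of them among the 3528, and 65 without the control array of replicate 4. It was 5 with slide as a fixed term, of which 0 were among the 3528. In that fit hmox1b was 2.67 (SE 1.80), manf 0.33, abcb11a −1.80, cyp2aa1 −0.09 and cat −0.04. By contrast, fgf19 (5.86), hspe1 (1.23) and hspd1 (0.87) were larger than as reported and atp7b was 1.33, but these lost the call as well.

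Ribosome biogenesis genes make and process ribosomal RNA in the nucleolus. In the 21 d nanoparticle arrays 27 of 71 rose and 0 fell (41 up and 1 down when adjusted over the list alone), among them polr1b (1.3, adjusted p = 0.00732) and nol11 (1.43, adjusted p = 0.00815). The median was 0.59 (camera 1.61e-11, fry 0.0424). Of 45 leukocyte markers 22 fell and 0 rose, with a median of −1.26 (camera 1e-09, fry 0.0424), including the T cell kinase lck (−2.16), the phosphatase ptprc (−2.04) and coro1a (−1.96). Of 73 genes of xenobiotic metabolism, which oxidise and conjugate foreign compounds, 1 rose and 20 fell (2 and 26 when adjusted over the list alone, median −0.52, camera 6.2e-05). Complement and coagulation genes had a median of 0.68, with 8 of 53 up and 1 down, among them the fibrinogen chains fgg (1.24) and fga (1.2). The unfolded protein response (6 up and 2 down of 42, median 0.33) and cell cycle (1 up of 71, median 1.52) were higher. Interferon response (5 of 40 down, −0.52), endothelial and stellate markers (7 of 28 down, −0.20) and the list of ribosomal proteins (−0.10) were lower. That list also holds S6 kinases, and of its 92 genes the 4 down were the kinases rps6ka1, rps6ka3a (−1.08) and rps6ka4 (−0.88), and rpl6. Hepatocyte markers had 4 of 34 up, such as mat1a (1.05), and a median of 0.35, or 0.14 with the 75th percentile shift, which ended the call.

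Markers of other tissues moved further in the same arrays. The intestine list had a median of −3.95, with 7 of 23 down (20 when adjusted over the list alone), and exocrine pancreas stood at −1.91, endocrine pancreas at −1.65 and muscle at −1.49. Gonad and germ cell markers had a median of 2.51, with ddx4 at least 2.67-fold higher (adjusted p = 0.0183) and rbpms2b at 2.40 (adjusted p = 0.0227). All 15 lists called by camera gave 0.671 with an estimated correlation, except ribosomal proteins at 0.712. Metal handling (6 up and 2 down of 32, camera 0.108), antioxidant and glutathione (2 up and 7 down of 56) and heat shock (3 up of 37) were not called as lists. The estrogen responsive list had a median of 1.16 and a mean of −0.163. With slide as a fixed term the medians were 0.21 for ribosome biogenesis (camera 0.0744), −0.42 for leukocyte markers, 0.22 for xenobiotic metabolism, −0.25 for intestine markers and 0.08 for gonad and germ cell markers, and 0.63 for complement and coagulation (camera 0.00248).

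**Figure D2:**
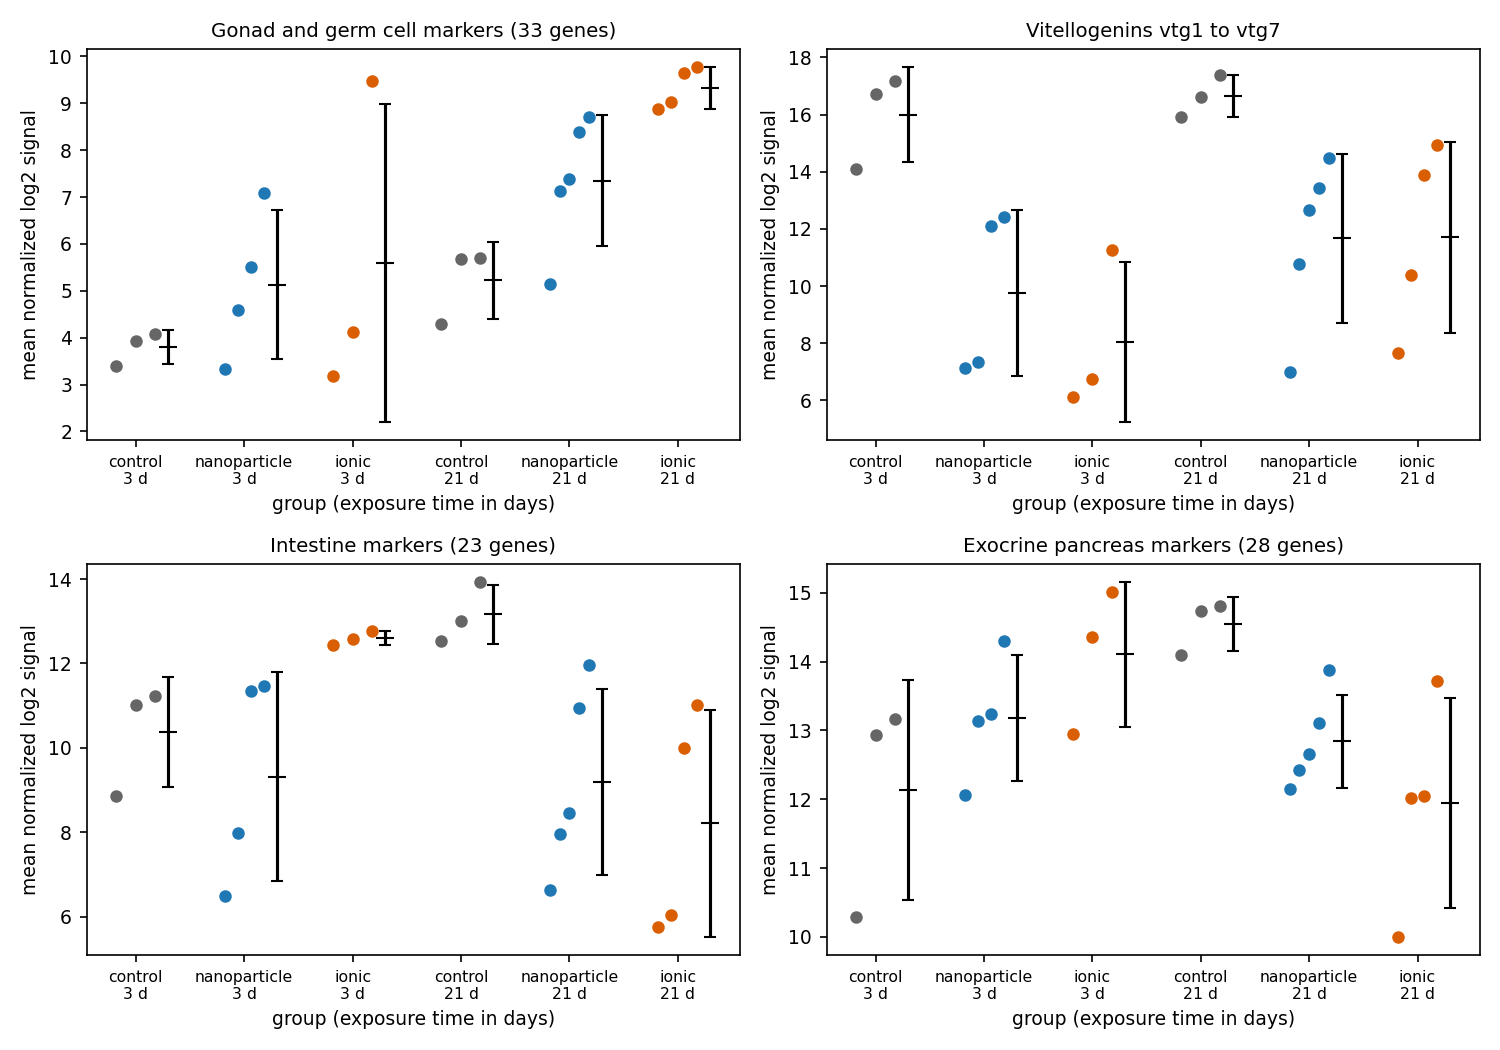
Mean log2 intensity on each array (points) of gonad markers, vitellogenins, intestine markers and exocrine pancreas markers in the 6 groups, with the group mean and SD (bars). The 4 ionic arrays of 21 d had gonad means of 8.87 to 9.77, above all 3 controls of that time at 4.28 to 5.70.

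Genes of the oocyte and of cell division were among those that rose after 21 d of ionic silver. The egg coat gene zp2l1 (7.92, adjusted p = 0.00416), the germ cell gene nanos3 (7.78, adjusted p = 0.00197), the mitotic activator cdc20 (7.55, adjusted p = 0.000327), btg4 (7.52) and the oocyte growth factor bmp15 (5.04, adjusted p = 0.000528) rose. Among the genes that fell were the lipid regulator pparaa (−3.50, SE 0.306, adjusted p = 3.77e-07), the triglyceride enzyme dgat2 (−2.45), cyp2aa1 (−3.40), abcg2a (−2.96), cyp1a (−1.41) and apoa1a (−2.29). The metal sensor mtf1 (−2.57, adjusted p = 2.11e-06), the zinc exporter slc30a1a (−1.87) and the oxidative stress factor nfe2l2a (−2.86) fell while mt2 rose, and cat fell (−0.81, adjusted p = 0.00591). The glutathione synthesis subunit gclm (1.29) and the chaperone dnajb6b (2.52) rose. Expression of the stress factor jun (−3.11), esr1 (−2.92), fetub (−1.57) and the histocompatibility gene mhc1uaa fell, the last with 1 of the 4 ionic arrays well above background. As with nanoparticles, pvalb9 (−7.32) and slc6a19b (−6.78) fell, but within slide they no longer passed (−5.91 and −6.34, adjusted p = 0.125 and 0.0823), nor did zp2l1 (adjusted p = 0.0528). Limma called 13151 genes, 66.0% of those tested, with 5773 up and 7378 down, and 11377 changed at least 2-fold. The median of all genes was −0.35, so many falls and rises are relative to a moved centre, and the 75th percentile shift moved that median by −0.381. Ranges did not overlap for 67.2% of genes (5.71% by chance). A fit within slide, which here rests on slide 4 with 1 control and 3 ionic arrays, called 9213 genes.

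With ionic silver at 21 d, 66 of 71 cell cycle genes rose and 2 fell (median 4.02, camera 4.12e-12), including dut (2.84) and rpa2 (2.3). Ribosome biogenesis followed with 51 of 71 up and 3 down (median 1.21), including nhp2 (2.77) and nol11 (3.1), and the proteasome with 25 of 56 up and 7 down (0.32). Gonad and germ cell markers had 21 of 33 up and 0 down (4.94), with rbpms2b at 4.17. Xenobiotic metabolism had 5 up and 59 down of 73 (−1.97), fatty acid oxidation 2 and 41 of 54 (−1.07), fatty acid synthesis 3 and 25 of 33 (−1.94), bile acid and sterol transport 0 and 19 of 26 (−2.05) and glucose metabolism 8 and 32 of 56 (−1.09). Oxidative phosphorylation (7 up and 41 down of 92, −0.46), ribosomal proteins (2 and 47 of 92, −0.38), antioxidant and glutathione (6 and 30 of 56, −0.85) and circadian clock (6 and 25 of 41, −1.27) were lower. The median of all genes was −0.35, with 7378 of 19933 called down. The medians of ribosomal proteins and oxidative phosphorylation lay close to it, so their falls are small against the moved centre. Complement and coagulation (1 up and 23 down of 53, −1.03), acute phase and inflammation (5 and 23 of 49, −1.12), interferon response (2 and 20 of 40, −1.41) and extracellular matrix (1 and 19 of 35, −1.4) were lower as well. So were the markers of hepatocytes (0 up and 19 down of 34, −0.89), exocrine pancreas (0 and 21 of 28, −2.73), intestine (0 and 19 of 23, −5.21), erythrocytes (4 and 18 of 28, −1.14), leukocytes (1 and 34 of 45, −2.01, with ptprc at −3.35), endothelial and stellate cells (1 and 20 of 28, −1.68) and bile ducts (2 and 16 of 20, −2.19). Lists not called by camera were metal handling (6 up and 11 down of 32), heat shock (12 and 7 of 37), unfolded protein response (9 and 12 of 42), DNA damage (22 and 12 of 52), cholesterol synthesis (2 and 12 of 27), estrogen responsive (10 and 9 of 24), endocrine pancreas (0 and 3 of 15) and muscle markers (3 and 4 of 39). Adjusted over the list alone, cell cycle had 66 up and xenobiotic metabolism 59 down. With an estimated correlation the 24 called lists gave 0.546 to 0.655, and fry called 28. Medians within slide were 3.98 for cell cycle, −1.8 for xenobiotic metabolism, −1.13 for fatty acid oxidation and 4.19 for gonad and germ cell markers, all called by camera.

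**Figure D3:**
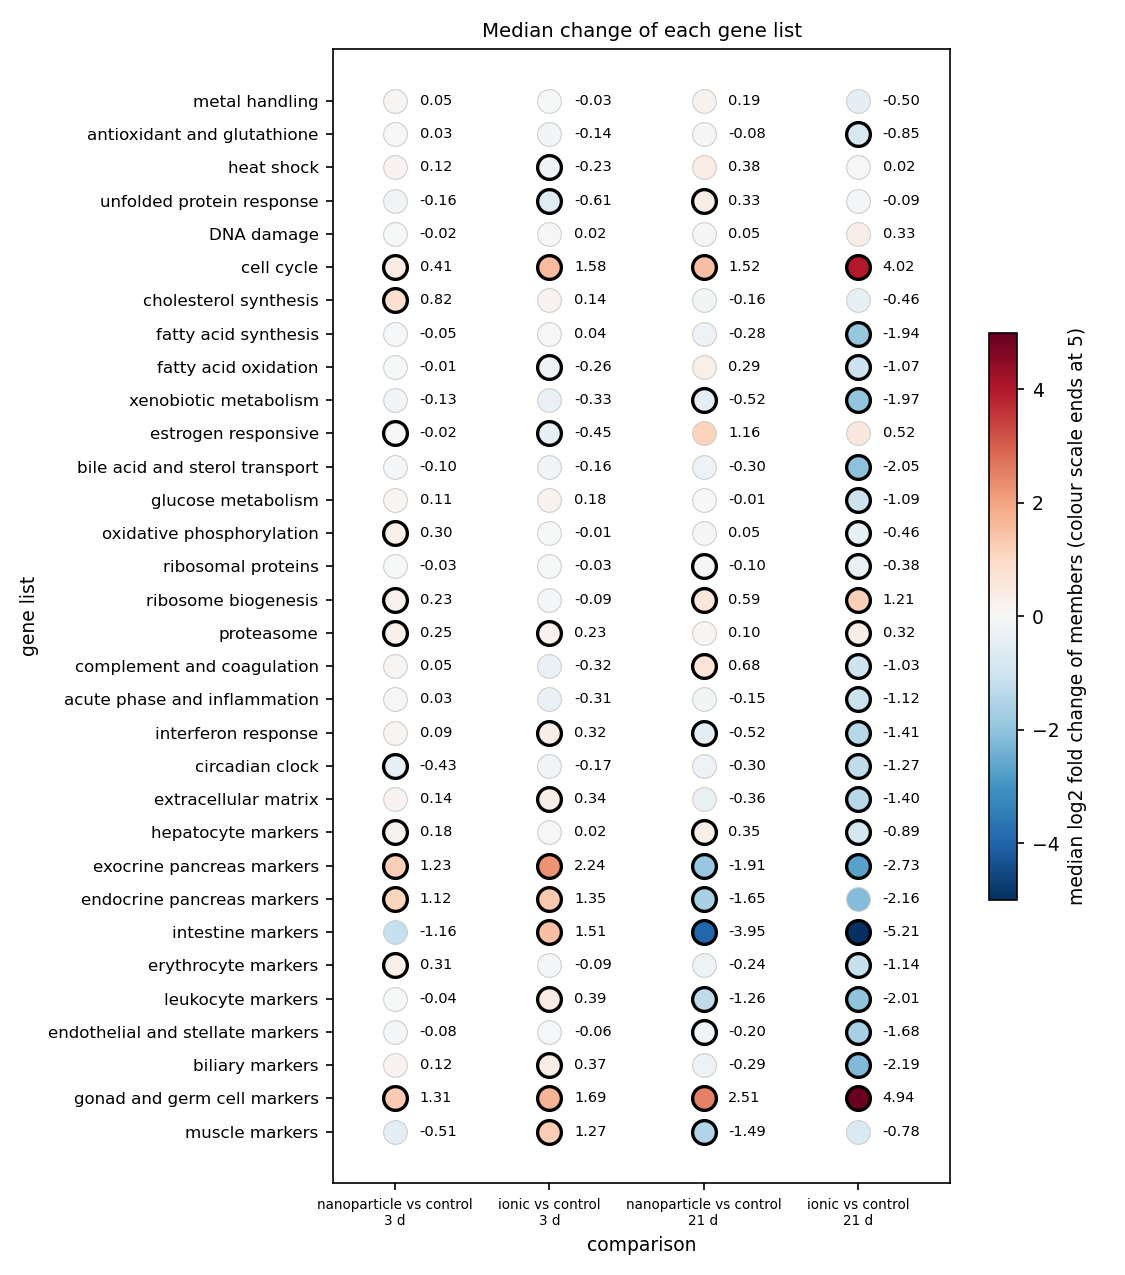
Median log2 fold change of each gene list (points) in the 4 comparisons with controls of the same time, with a ring where camera with a preset correlation passed at 0.05. The cell cycle list stood at 4.02 and the intestine list at −5.21 in the 21 d ionic arrays.

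Many genes of fat and sugar metabolism were higher with nanoparticles than with ionic silver at 21 d. Fatty acid synthesis had 24 up and 4 down of 33 genes, and glucose metabolism 29 up and 4 down of 56. The fatty acid synthesis enzyme acaca (3.13, SE 0.297, adjusted p = 2.16e-06), dgat2 (2.34), the gluconeogenic enzyme pck2 (2.05, adjusted p = 1.13e-06) and mat1a (2.16) were higher, and so were cat (1.51), cyp1a (1.44), atp7b (2.1) and mtf1 (2.06). The iron hormone hamp (3.51, adjusted p = 0.00921) and mhc1uaa were also higher, as was hmox1a (1.91, adjusted p = 0.0397), which did not pass within slide (2.44, adjusted p = 0.199). The chromatin protein hmgb2a (−2.35), dut (−2.14), nhp2 (−1.79), bmp15 (−2.73), rbpms2b (−1.78) and il13ra2 (−4.46, adjusted p = 0.00122) were lower. Of 54 fatty acid oxidation genes 46 were up and 2 down (median 1.45, camera 7.12e-10), of 53 complement and coagulation genes 44 up and 1 down (1.44), and of 34 hepatocyte markers 28 up and 0 down (1.4). Xenobiotic metabolism (46 up and 4 down of 73, 1.37) and metal handling (16 up and 4 down of 32, 0.70) were higher, whereas cell cycle (1 up and 51 down of 71, −2.35), ribosome biogenesis (6 up and 39 down, −0.67) and gonad markers (0 up and 5 down of 33, −2.11) were lower. Limma called 10912 genes, 5929 up and 4983 down, against a median of all genes of 0.16. Ranges did not overlap for 39.4% (1.59% by chance). The 24 lists called by camera gave 0.511 to 0.713 with an estimated correlation. Fitted within slide, the medians were 1.78 for fatty acid oxidation and −4.02 for cell cycle. That fit rests on slide 5, with 1 ionic array (replicate 5) and 2 nanoparticle arrays. The cell cycle mean was 11.3 on that ionic array, the highest of its group, and 6.165 and 8.835 on the 2 nanoparticle arrays.

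Both exposures at 21 d shared 3103 genes called the same way, 1310 up and 1793 down, against 438.5 and 745.5 from independent draws, and 34 were called in opposite directions. The shared count was 63 without control replicate 4, 32 with scan day as a fixed term and 5 with slide as a fixed term. The correlation of the effects across genes was 0.808, against 0.563 in 100 simulations without exposure effects, and the covariance of 2.08 lay above the simulated range of 0.017 to 0.765. These simulations kept the shared controls, and their shared count averaged 0.01 with a highest of 1. They hold no exposure effects, and the 3 controls were too few to split, so part of the excess of shared calls over independent draws, at 21 d as at 3 d, may come from the shared controls.

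**Figure D4:**
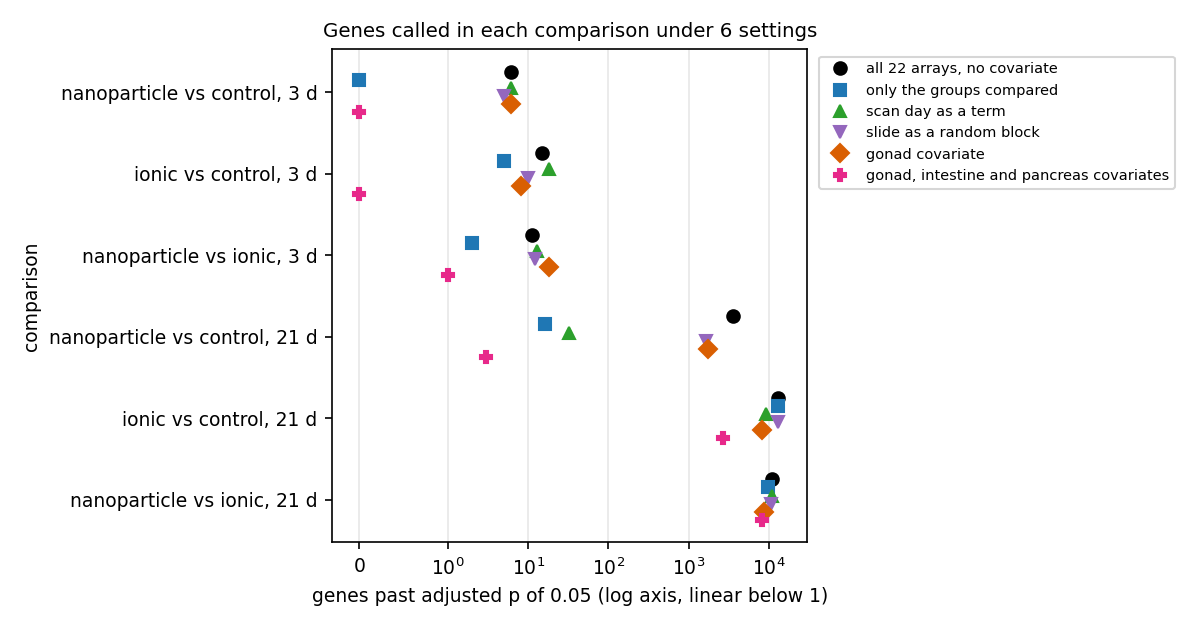
Genes called (adjusted p under 0.05, log axis, linear below 1) in the 6 comparisons of groups of the same time under 6 settings. The 21 d nanoparticle count was 3528 as reported, 1660 with slide as a random block and 32 with scan day as a fixed term.

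The exposure effect differed between 3 and 21 d in a direct test for igf3, gfra4a and fgf13b with nanoparticles, and for serpinh1b and pparaa among others with ionic silver. For nanoparticles igf3, a gonadal growth factor (3.89, adjusted p = 0.0239), the neurotrophic receptor gfra4a (adjusted p = 0.034, with 0 arrays well above background in the 3 d nanoparticle and 21 d control groups) and fgf13b (3.46, adjusted p = 0.0453) were among 6 genes called, 5 up and 1 down, with 2902 at an unadjusted p under 0.05. For ionic silver 8274 were called, 3984 up and 4290 down. Among them serpinh1b was higher (2.21, adjusted p = 0.00105), and pparaa (−3.46), abcg2a (−3.01), the gut amino acid carrier slc6a19b (−13.86), the ileal bile acid binder fabp6 (adjusted p = 0.00896) and the gut hormone insl5a were lower. Over the settings slc6a19b ran from −14.87 to −5.99, fabp6 from −20.06 to −3.42 and insl5a from −12.72 to −4.09, and for insl5a 1 of the 3 control arrays of 3 d and 1 of the 4 ionic arrays of 21 d were well above background. The exocrine pancreas and intestine lists moved by −4.85 and −6.72 in the same test. With slide as a fixed term, which here gives the same estimates as within slide, 18 genes passed for ionic silver. The ionic genes named here lost the call in that fit, with serpinh1b at 2.45, pparaa at −2.455, abcg2a at −2.55 and slc6a19b at −13.15. With slide as a fixed term igf3, gfra4a and fgf13b no longer passed either, at 2.96 (SE 1.29), 2.38 (SE 1.48) and 2.77 (SE 1.45) (adjusted p = 0.486, 0.596 and 0.539).

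Controls at 21 d differed from controls at 3 d in 189 genes, among them egr2a, slc15a2 and thrsp. Expression of egr2a (−5.06, adjusted p = 0.0246), ier2a (−2.50), the hormone-responsive factor zbtb16a (−3.79), the muscle-type fatty acid carrier cpt1b (−3.64) and serpinh1a (−2.12) fell. The peptide carrier slc15a2 (6.04, adjusted p = 0.0197), the lipogenic factor thrsp (5.25) and taldo1 (1.88) rose, as did pitx1 (adjusted p = 0.00953), for which 1 of the 3 arrays of 3 d was well above background. Of 54 fatty acid oxidation genes 1 was up and 20 down when adjusted over the list alone (median −0.59). Exocrine pancreas markers had a median of 2.67, with 24 of 28 up and 1 down when adjusted over the list alone (camera 7.53e-14, and not called with an estimated correlation). Intestine markers stood at 2.28. Of the genes called 49 were up and 140 down, with ranges apart for 37.1% of genes (10% by chance). The count ran from 2 to 661 as single arrays were left out, and was 1 with slide as a fixed term.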

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

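Except for the test of gonad RNA and the refits to other splits of the arrays, the tests in this part were chosen after the result was seen.

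Of 140 groups of 4 or 5 arrays tested for an array far from the others, 7 had one, and chance flags about 1 in 20 groups. The nanoparticle array of replicate 3 at 3 d had a median local background of 72, against 24.5 to 26 in its group, and its negative control spots had a net signal of 74.5 against 20 to 23.1. The ionic array of replicate 3 at 21 d had a background of 24.5, where the others had 26. For hsp70l the nanoparticle array of replicate 2 at 3 d stood at 6.43, with the others at 7.34 to 7.49. For insl5a the ionic array of replicate 2 at 21 d stood at 6.89, with the others at 2.25 to 2.77. For itln2 the nanoparticle array of replicate 2 at 21 d stood at 6.41, with the others at 1.51 to 1.62. For mhc1uaa the nanoparticle array of replicate 5 at 21 d stood at 4.67, with the others at 6.76 to 7.59.

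A direct test found 6 genes whose nanoparticle effect differed between 3 and 21 d. Among them igf3 differed by 3.89, gfra4a by 5.1 and fgf13b by 3.46, and the size for gfra4a depends on the floor, as 2 of its 4 groups were not well above background. The highest count among the other splits was 2169, several times the 6 of the real split, which points to a structure of the samples. Of 100 splits 2 gave as many genes. These splits mix exposed and control arrays within each time, so they stand for no exposure effect at either time. They cannot decide whether the 6 genes differ between times by chance, and an unevenness of the arrays is not excluded.

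The same test for ionic silver called 8274 genes. The mt2 effect was larger at 21 d by 3.26 and that of serpinh1b by 2.21. The effects on fabp6 (−17.38), slc6a19b (−13.86), insl5a (−11.40), pparaa (−3.46) and abcg2a (−3.01) were lower at 21 d. Over the settings fabp6 ran from −20.06 to −3.42, slc6a19b from −14.87 to −5.99 and insl5a, which was near the floor on most arrays of 2 groups, from −12.72 to −4.09, so these sizes are uncertain. Of 100 splits 5 gave a count as large, with 11186 as the highest other, so chance could not be excluded. With slide as a fixed term 18 genes passed, and the genes named here were not among them.

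The 13151 genes called between ionic silver and control at 21 d were 66.0% of those tested, and included 66 of 71 cell cycle genes and 21 of 33 gonad and germ cell markers that rose. RNA of gonad cells is a candidate explanation. Across 19809 genes without the markers, the ionic fold change correlated with the slope on the gonad marker mean within the other 5 groups (r 0.658), where genes are not independent replicates. That slope leans most on the ionic arrays of 3 d, where replicate 1 had a gonad mean of 9.48 against 4.12 and 3.18 in the others. RNA degradation was argued against by 5′ to 3′ probe ratios that differed by 0.0549. The choice of normalization was argued against by 94.9% of the genes being called the same way with the 75th percentile shift. That shift also scales out brightness, so it cannot decide whether the brightness of the arrays played a part. A response of liver to silver stays open and untested, since all 4 ionic arrays had gonad marker means above all 3 controls.

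Immediate early genes were lower in both exposures than in controls at 3 d, with means over egr1, egr2a, dusp2, ier2a and ier2b of 10.72 ± 0.57 in controls, 6.47 ± 0.42 with ionic silver and 6.89 ± 0.62 with nanoparticles. The slide of the 3 d controls stays open as a cause, because the only exposed array on that slide, an ionic one, lay below them too (−4.73) but 1 array excludes nothing. The 21 d controls also lay below the 3 d controls (−3.26), so 3 d control fish sampled in another state may explain the difference, although the 5 genes were picked from comparisons with the same 3 d controls, which favours a difference of this sign. On most exposed arrays egr1 was not well above background, so the exposed means depend in part on the floor. An effect of silver stays open, as no other control group of 3 d was measured here.

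Vitellogenin means were lower in exposed than in control arrays at both times. The choice of normalization was argued against by a median of −6.76 for nanoparticles at 3 d with the 75th percentile shift. Brightness itself was not tested by it, because that shift also scales brightness out. Fewer female fish in the exposed pools, against labels that give males, and a lower estrogen response to silver cannot be told apart. Gonad marker means did not fall along with vitellogenins on the ionic arrays of 21 d (8.87 to 9.77, against 4.28 to 5.70 in controls). At 3 d the ionic arrays stood at 9.48, 4.12 and 3.18, against 3.39 to 4.08 in controls. Over 22 arrays the deviations from group means of vitellogenin and gonad markers had r −0.128 (permutation p = 0.577) and rho −0.13 (permutation p = 0.561), and r −0.0912 without the 2 arrays farthest from the median.

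Refits to other splits of the arrays were each judged alone at a share of 0.05, without adjustment over the comparisons. The share was smaller for the 3528 genes of nanoparticle against control at 21 d (1 of 56 splits, highest other 2043). So it was for the 13151 genes of ionic silver at 21 d (1 of 35, highest other 10990). For the 10912 genes between exposures at 21 d it was smaller too (2 of 100), although another split called more genes (11505). The share was also smaller for the 24 gene lists between exposures at 21 d (3 of 100), although another split called 24 as well. These shares make chance less likely and do not exclude it. Against controls at 21 d they cannot tell exposure from scan day, as 2 of the 3 controls were scanned apart from all exposed arrays. Chance could not be excluded for the 6 genes of nanoparticle against control at 3 d (2 of 35, highest other 13), nor for its 12 lists (13 of 35, highest other 17). It could not be excluded for the 11 genes between exposures at 3 d (3 of 35), where another split called 385, which points to a structure of the samples, nor for its 14 lists (14 of 35, highest other 19). The same held for the 15 lists of nanoparticle against control at 21 d (10 of 56, highest other 22) and the 24 lists of ionic silver at 21 d (3 of 35, highest other 25). With 10 splits a share under 0.05 cannot be reached for the 15 genes (highest other 5) and 15 lists (highest other 17) of ionic silver at 3 d, or for the 189 genes between controls (highest other 1).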

How the results depend on the processing

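The present filter, the covariate fits and the fits without doubted arrays were chosen after the data were seen. In this part a comparison with control is named by its exposure and time, and the time effect of an exposure is its effect at 21 d minus that at 3 d. Apart from the 22 settings that leave out 1 array, counts of genes moved beyond 1.5 times in 78 cases and stayed within it in 104. Counts of lists did so in 17 and 111 cases, and counts of shared genes in 20 and 19. In the same settings values of named genes kept their side of the threshold in 2210 cases, whatever the sign of a gene that passed under neither setting. They lost the call in 465, gained it in 20, and lost it with a change of sign in 3. Where a cause is not named, the cause was not tested. The deposited text names no test, so no fit with the authors' test was run. A nanoparticle value within slide could not be had against controls of the same time.

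The rise of mt2 at 21 d passed in all settings run for ionic silver, and in all but slide as a fixed term for nanoparticles (2.03, SE 0.591, adjusted p = 0.972). For cat (−0.042) and vtg3 (0.39) the nanoparticle value at 21 d no longer passed and changed sign with slide as a fixed term, as did zp2l1 of ionic silver at 21 d with gonad, intestine and pancreas covariates (−0.11).

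Camera with an estimated correlation called 0 lists in each of the 6 comparisons of groups at the same time. Fry called 2 for nanoparticle 3 d, 0 for ionic 3 d, 2 for nanoparticle 21 d and 1 between exposures at 3 d.

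Scaling by the 75th percentile moved the median of all genes by −0.381 for ionic 21 d, 0.301 between exposures at 21 d and −0.318 for the ionic time effect. It left 3 genes for the nanoparticle time effect, all of them up (100% against 83.3%), and the share up was 0 against 16.7% for nanoparticle 3 d. Among called lists the share up was 69.2% against 83.3% for nanoparticle 3 d, 42.9% against 73.3% for ionic 3 d and 72.2% against 57.1% between exposures at 3 d.

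Normexp background correction moved that median by 0.235 for ionic 21 d and 0.102 for the ionic time effect. It gave 34 genes for nanoparticle 3 d (32.4% up), 102 for ionic 3 d, 72 between exposures at 3 d, 24 for the nanoparticle time effect (33.3% up), 644 between controls (37% up against 25.9%) and 15 shared at 3 d.

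With no filter on dim probes 13 genes passed for nanoparticle 3 d, 34 for ionic 3 d and 9 were shared at 3 d. The stricter filter gave 3 for nanoparticle 3 d and 3 for the nanoparticle time effect, with fewer genes tested. The present filter gave 20 for the nanoparticle time effect. Testing every probe gave 11 genes and 19 lists for nanoparticle 3 d, 36 genes for ionic 3 d, 25 lists for nanoparticle 21 d, 22 genes between exposures at 3 d and 11 for the nanoparticle time effect.

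Fits with fewer arrays had fewer degrees of freedom. Only arrays of the same time gave 0 genes for nanoparticle 3 d, 0 for ionic 3 d, 2315 for nanoparticle 21 d and 0 shared at 3 d. Only the groups compared gave 0 for nanoparticle 3 d, 5 for ionic 3 d, 16 for nanoparticle 21 d, 2 between exposures at 3 d, 115 between controls, 0 shared at 3 d and 13 shared at 21 d.

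Pairs with the same replicate number had a median correlation of −0.049 at 3 d and 0.124 at 21 d, against 0.064 and −0.005 for other pairs. Pairing by number was thus not seen at 3 d and stays open at 21 d. With replicate number as a block 1 gene passed for nanoparticle 3 d, 0 for ionic 3 d, 1 between exposures at 3 d, 31 between controls and 0 were shared at 3 d. Slide as a random block gave 9 lists for ionic 3 d, 1660 genes for nanoparticle 21 d, 1 for the nanoparticle time effect and 14 between controls, and 1467 were shared at 21 d.

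Slide as a fixed term gave 353 genes for nanoparticle 3 d (76.5% up against 16.7%), 1886 for ionic 3 d (62.1% up against 13.3%), 5 for nanoparticle 21 d, 2 between exposures at 3 d, 1 for the nanoparticle time effect, 18 for the ionic time effect and 1 between controls. Shared genes were 319 at 3 d (77.7% up against 0) and 5 at 21 d. The share of called lists that were up was 40% against 83.3% for nanoparticle 3 d, 41.7% against 73.3% for ionic 3 d and 31.2% against 57.1% between exposures at 3 d. For nanoparticle 21 d it moved the other way, to 81.8% against 40%. The nanoparticle contrasts then rest on chains of slides. A fit within slide gives the same estimates as the slide term wherever the groups compared share a slide, so it is no separate check. For ionic 3 d these estimates rest on ionic replicate 1 alone. With scan day as a fixed term 32 passed for nanoparticle 21 d (3.12% up against 42.9%) and 12 for the nanoparticle time effect (8.33% up against 83.3%). In that fit 4558 passed for the ionic time effect and 661 between controls, and 32 were shared at 21 d.

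Array weights gave 718 genes for nanoparticle 3 d (51.3% up), 540 for ionic 3 d, 6474 for nanoparticle 21 d, 860 between exposures at 3 d, 831 for the nanoparticle time effect and 5012 between controls, with 108 shared at 3 d and 5543 at 21 d. An adjusted p under 0.01 left 3 for nanoparticle 3 d, 6 for ionic 3 d, 482 for nanoparticle 21 d, 7 between exposures at 3 d, 1 for the nanoparticle time effect, 4771 for the ionic time effect and 9 between controls. It left 15 lists between exposures at 21 d, 2 shared genes at 3 d and 440 at 21 d.

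A gonad covariate gave 8 genes for ionic 3 d, 1738 for nanoparticle 21 d, 8147 for ionic 21 d, 18 between exposures at 3 d, 54 for the nanoparticle time effect and 1230 shared at 21 d. With gonad, intestine and pancreas covariates 0 passed for nanoparticle 3 d and 0 for ionic 3 d. The other counts were 3 genes and 9 lists for nanoparticle 21 d, 2661 genes and 15 lists for ionic 21 d, 1 gene between exposures at 3 d, 723 for the ionic time effect, 0 between controls, 0 shared at 3 d and 3 shared at 21 d.

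Without the 2 arrays of 3 d with most gonad RNA 3 genes passed for ionic 3 d, 17 between exposures at 3 d and 13 for the nanoparticle time effect, and 0 were shared at 3 d. Without the ionic 21 d arrays 8 passed for ionic 3 d and 1 for the nanoparticle time effect. Leaving out 4 nanoparticle arrays of 21 d kept replicate 1 alone, chosen for its gonad marker mean of 5.15, nearest the controls, and assumed to vary like the other groups. It gave 573 genes for nanoparticle 21 d, 22 between exposures at 3 d, 15 for the nanoparticle time effect and 345 between controls, with 15 lists between exposures at 21 d, 2 shared genes at 3 d and 357 at 21 d.

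Leaving out each array in turn gave 2 to 24 genes and 9 to 13 lists for nanoparticle 3 d, with 2 without nanoparticle replicate 1 or 5 and 24 without replicate 2. For ionic 3 d it gave 0 to 33 genes and 8 to 17 lists. There 8, 5 and 6 genes passed without control replicates 3, 4 and 5, and 0, 9 and 33 without ionic replicates 1, 3 and 5. The 8 lists came without control replicate 4 or ionic replicate 5. Between exposures at 3 d the range was 6 to 23 genes and 9 to 18 lists, with 6 without ionic replicate 1 or nanoparticle replicate 5, 23 without nanoparticle replicate 3, and 9 lists without ionic replicate 5. Shared genes at 3 d ran from 0 to 6, with 0 without ionic replicate 1 and 1 without nanoparticle replicate 1 or 5. The named 3 d ionic calls all ended without ionic replicate 1. In each of these fits serpinh1b and miox passed between exposures, and dusp2 with nanoparticles.

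For nanoparticle 21 d leaving out single arrays gave 65 to 4614 genes and 14 to 16 lists, with 676 and 65 without control replicates 1 and 4, and 2185 and 1883 without nanoparticle replicates 4 and 5. Among the named genes mt2 and sult2st3 alone passed without control replicate 4. For ionic 21 d the range was 11927 to 13043 genes and 22 to 25 lists. The value for cat, ionic vs control, 21 d, no longer passed without control replicate 5 (−0.59, adjusted p = 0.0507). Between exposures at 21 d it was 9273 to 11784 genes and 22 to 25 lists, with bmp15 and rbpms2b lost without nanoparticle replicate 1. Shared genes at 21 d ran from 63 to 4259, with 629 and 63 without control replicates 1 and 4 and 1944 and 1591 without nanoparticle replicates 4 and 5.

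The nanoparticle time effect ran from 1 to 57 genes, with 3, 3 and 1 without 3 d control replicates 3, 4 and 5, and 39 and 3 without 3 d nanoparticle replicates 2 and 5. It was 2, 2 and 57 without 21 d control replicates 1, 4 and 5, and 54, 3 and 2 without 21 d nanoparticle replicates 2, 3 and 4. The ionic time effect ran from 6414 to 9818. Between controls the range was 2 to 661, with 15, 6 and 30 without 3 d replicates 3, 4 and 5, and 2, 3 and 661 without 21 d replicates 1, 4 and 5. Signal over background limits genes such as egr1 and cldn7a, where one group was not well above background, to bounds.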

Other observations

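The covariate fits in this part were chosen after the result was seen, and the correlations with the gonad slope before.

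The gonad and germ cell list holds ovary, egg and testis genes, such as those for egg coat proteins and germ granule helicases, which a liver makes at low levels. Its mean log2 intensity was 9.77, 8.87, 9.03 and 9.65 on the 4 ionic arrays of 21 d. On the nanoparticle arrays of 21 d it was 5.15, 7.12, 8.70, 7.39 and 8.38, and on the controls of that time 5.70, 4.28 and 5.68. At 3 d the ionic array of replicate 1 stood at 9.48 and the nanoparticle array of replicate 3 at 7.09. The first principal component over all arrays held 55.9% of the variance and correlated with the gonad marker mean at a Pearson r of 0.941. For components 2 and 3, r was 0.126 and 0.238. The gonad means differ between exposure groups, so these values do not separate RNA of gonad cells from an exposure effect. Across 19809 genes, the fold changes of each comparison correlated with the slope on the gonad mean, taken within the 4 groups outside the comparison, at 0.447 and 0.593 for nanoparticle and ionic silver at 3 d, 0.479 and 0.649 at 21 d, and −0.312 and −0.573 between exposures at 3 and 21 d. Except where the ionic arrays of 3 d were part of the comparison, the slope leans largely on their replicate 1.

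With the gonad covariate the ribosome biogenesis median of nanoparticle against control at 21 d was 0.55 (camera 3.85e-08) and that of leukocyte markers −1.02 (camera 3.02e-09). With gonad, intestine and pancreas covariates they were 0.32 and −0.18 (camera 0.000268 and 0.0194). The log2 fold change of mt2, nanoparticle vs control, 21 d, was 2.61 (adjusted p = 0.000411) with the first and 2.64 (adjusted p = 0.0415) with all 3 covariates. These covariates lie partly along the exposures, so a smaller change with them does not separate an exposure effect from RNA of other tissues.

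Intestine markers moved apart from the gonad markers at 21 d, with list medians of −3.95 for nanoparticles and −5.21 for ionic silver. With all 3 marker covariates 3 genes passed for nanoparticle against control at 21 d, all 3 among the 3528. For ionic silver 2661 passed, of which 2628 were among the 13151.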
